A study of Homo sapiens with 6 samples.

How the data were processed

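Gene expression was measured in kidney organoids, which are clusters of nephron-like and stromal cells grown from H9, an established human embryonic stem cell line. Per the labels, 1 line was PKHD1-/- (clone C51) and 1 was PKHD1+/- (clone C9). PKHD1 is the gene mutated in autosomal recessive polycystic kidney disease. Organoids of each genotype were grown in 3 cultures and harvested at day 35. In the flow culture they lay on an engineered matrix of gelatin and fibrin under medium flowing at 4.27 ml/min from day 15. In the static culture they lay on the same matrix with no flow. In the forskolin culture they received 20 µM forskolin, an activator of adenylyl cyclase, from day 14, and the labels do not say that they lay on the matrix. Total RNA was amplified, coupled to Cy5 and hybridized to 3D-Gene Human 25k oligonucleotide arrays, 1 array for each genotype and culture.

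The deposited scanner files give the intensity of each spot as its median brightness, on a linear scale with no background subtracted, per the file headers. Each of the 6 files holds 27456 spots, of which 2680 are blank. The authors' value table gives an intensity per probe that was found to be a straight line of the spot median of the same array, with 0 at the trimmed mean of the blank spots. The median of its values is 25 on every array, and cells are empty below about 2.0 SD of the blank spots above that level. The comparisons start from the scanner files, and the value table serves as an alternative. The local background column was not subtracted because it follows the spot itself, with rank correlations from 0.965 to 0.990.

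Spot medians were corrected by the normexp method with an offset of 50, put on a log2 scale and quantile normalized between the 6 arrays (limma 3.58.1 in R 4.3.3). Of 24460 probes, 20236 carry 1 gene symbol and 4224 carry none, and the latter were counted but not analysed by gene. Symbols were brought to current names where the reference allowed it: 17238 were current, 2899 were updated and 99 were kept as listed. The 205 probes marked as not good on any array were left out. Probes of a gene were averaged, which gave 17446 genes. A gene was tested when it lay above background on at least 2 of the 6 arrays. This kept 16365 genes and left out 1081, and 14741 lay above background on all 6 arrays. An array gives no count of molecules, so the number of arrays limits the precision.

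Genes were compared with limma's moderated test in the model culture plus genotype over all 6 arrays, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The genotype term compares 3 arrays with 3, paired by culture. The flow and forskolin terms each compare 2 arrays with the 2 static arrays, paired by genotype. The fit has 2 residual degrees of freedom and a prior worth 1.54, so the spread of each gene is drawn towards that of all genes. A value after ± is limma's moderated SE, which uses this spread over all 6 arrays. It is not the SE of the 2 or 3 pairs alone. Since no group holds more than 1 array, the spread is what culture and genotype leave over, and the p-values measure only that. A genotype difference that varies between cultures therefore counts as spread, and cannot be told apart from variation between samples, which may be technical. Genotype differences within a culture, and flow responses within a genotype, rest on single arrays. They were not tested and are given as values. For these, the median of a gene list is given with its percentile among 10000 random lists of the same size, matched on mean intensity in 20 bins. The random lists draw genes singly, so a percentile takes genes as independent and measures no spread between samples.

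Gene lists numbered 31, of which 17 hold pathway genes and 14 hold markers of cell types of the kidney and of other tissues. They were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. List shifts were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and tested again with an estimated correlation and with fry. The rule names PKHD1, FOS and RAC1 always, the last 2 from prior knowledge of published work on such organoids and not from the labels. For each tested comparison it names the 10 genes with the largest change in each direction among those past the threshold with 1 sign in every pair of arrays. Where fewer than 10 pass, it fills up to 10 with genes above background on the brighter side whose smallest paired change is largest. For the difference of the flow responses it names the 10 largest and 10 smallest values. From a list described it names members past the threshold, or else the 2 to 4 members with the largest change. Placeholder names were not named.

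The procedure was tested on simulated data with 200 changed genes in each of 10 runs, drawn from the fitted spread. For the genotype term it found 60.0% of genes changed by 1 on the log2 scale, 86.0% of those changed by 2 and 97.1% of those changed by 4, with 8.2 false calls per run. For the flow term these shares were 43.4%, 79.4% and 93.8%, with 6.2 false calls. For the forskolin term they were 37.5%, 78.8% and 91.1%, with 8.1 false calls. The spread was drawn from the fitted prior after a first version, drawn from each gene's own fitted spread, proved too even. A shifted list was found in 10 of 10 runs. Noise was drawn independently between genes there, so these runs do not test lists whose members vary together. The simulated spreads also followed the prior that limma's test assumes, and culture and genotype added up without any shared deviation. The shares found hold for such data and may not hold for the real arrays.

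The alternatives were scaling to the 75th percentile, cyclic loess, no background correction, an offset of 10, the authors' value table, no filter, and a filter on all 6 arrays. Others were trend and robust settings, other thresholds, the brightest probe of each gene, fits without a culture term, and fits without each array or pair. Forskolin was also compared with flow and with the mean of flow and static. Leaving out each array for the list tests was added after the data were seen. A test for probe GC content was not run, since no probe sequences were at hand. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.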

Results

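Messenger RNA was profiled on 6 single-colour arrays of day 35 kidney organoids, 1 for each combination of 2 genotypes (PKHD1-/- and PKHD1+/-) and 3 cultures (static, flow and forskolin). No group has replicates, and 1 clone stands for each genotype, so clone and genotype cannot be told apart. The median spot lay 39.6 intensity units above the blank spots for PKHD1-/- flow, 58.2 for PKHD1+/- flow, 33.6 for PKHD1-/- static and 37.1 for PKHD1+/- static. It lay 16.5 and 21.1 units above for PKHD1-/- and PKHD1+/- forskolin, which were the dimmest arrays. The share of probes with a value in the authors' table ran from 83.4% to 94.1%. Correlations between arrays across genes ran from 0.916 to 0.982. The PKHD1-/- flow array was closer to the PKHD1+/- static array (0.976) than to the PKHD1-/- static array (0.968). Likewise, the PKHD1+/- flow array was closer to the PKHD1-/- static array (0.980) than to the PKHD1+/- static array (0.972).

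The targeted gene, PKHD1, encodes fibrocystin, a membrane protein of the primary cilium. Its normalized log2 intensity was 7.37 in PKHD1-/- flow, 7.41 in PKHD1+/- flow, 7.35 in PKHD1-/- static, 7.49 in PKHD1+/- static, 7.33 in PKHD1-/- forskolin and 7.24 in PKHD1+/- forskolin. The genotype difference was -0.03 ± 0.07 (SE, n = 3 pairs). The labels do not say which part of the gene was changed, and the position of the 2 PKHD1 probes was not known, so these levels neither bear out nor contradict the genotypes. The 2 probes differed on every array, and most on the forskolin arrays: in PKHD1-/- one read 5.97 and the other 8.69, against 6.55 and 8.14 in static culture. Before normalization both spots were dimmer with forskolin, at 49.5 and 236 against 87.6 and 283 in static culture. The first lay near the blank mean of that forskolin array, 44.4.

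RAC1, a small GTPase that organizes the actin cytoskeleton, and FOS, an immediate early transcription factor of the AP-1 complex were named before the data were examined, from prior knowledge and not from the labels. RAC1 read 11.17 in PKHD1-/- and 11.46 in PKHD1+/- under flow, 11.41 and 11.94 in static culture, and 11.64 and 11.61 with forskolin. FOS read 9.59 in PKHD1-/- and 11.51 in PKHD1+/- under flow, 10.43 and 10.78 in static culture, and 6.95 and 7.29 with forskolin. Neither gene passed the threshold in any of the 3 tested comparisons.

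**Figure D1:**
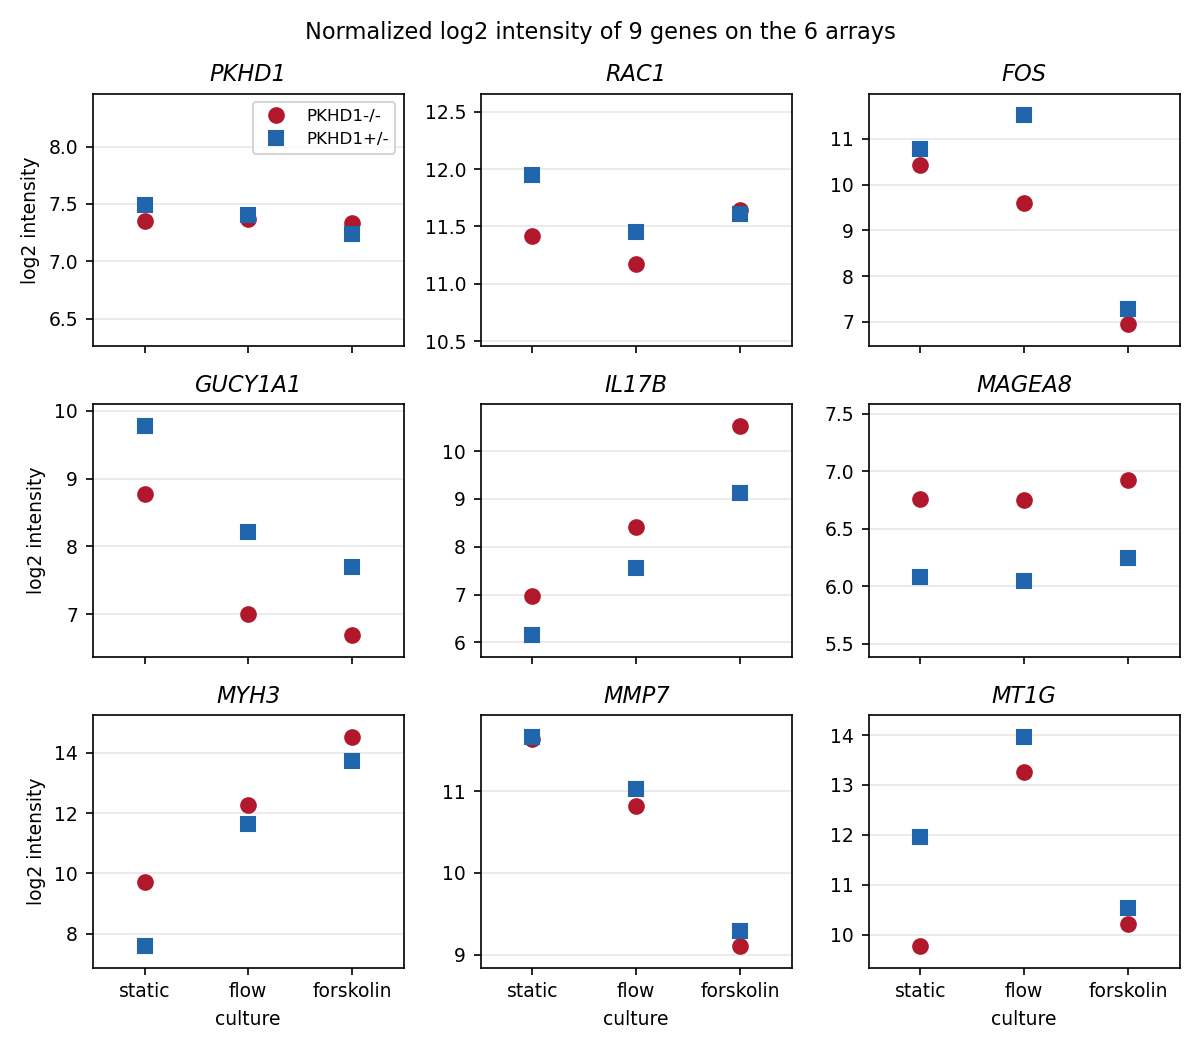
Normalized log2 intensity (vertical axes, each panel with its own range) of 9 genes on the 6 arrays, by culture (horizontal axes), with 1 point per array for PKHD1-/- (circles) and PKHD1+/- (squares). FOS lies lowest on the forskolin arrays (6.95 and 7.29), and GUCY1A1 lies lower in PKHD1-/- than in PKHD1+/- in each culture.

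The first comparison asks what the loss of the remaining PKHD1 copy changes in organoids across the 3 cultures. Among the genes with the largest minimum difference over the 3 pairs, values were higher in PKHD1-/- for IL17B, a cytokine gene, at 1.02 ± 0.15 on the log2 scale (SE, n = 3 pairs), and KLHL41, a sarcomere protein gene, at 1.40 ± 0.34. They were lower for GUCY1A1, a subunit of the nitric oxide receptor soluble guanylate cyclase, at -1.07 ± 0.07, and IGFBP7, a secreted binding protein for insulin-like growth factors, at -0.85 ± 0.14. None of these passed the threshold (adjusted p = 1.00 for each). The rule that named them requires 1 sign in 3 of 3 pairs, which 20.8% of all genes tested had. FOS was lower in PKHD1-/- in 3 of 3 pairs, at -1.93 under flow, -0.35 in static culture and -0.34 with forskolin, and its mean difference of -0.87 ± 0.40 did not pass (adjusted p = 1.00).

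Among the other genes higher in all 3 pairs, the cancer-testis antigen genes MAGEA8 and MAGEA4 differed by 0.69 ± 0.05 and 0.76 ± 0.09. The embryonic myosin MYH3, the slow troponin TNNT1 and the muscle gene SMPX differed by 1.19, 0.93 and 0.83. KREMEN2, a receptor for DKK proteins, CTSK, a protease of the extracellular matrix, and OGN, a matrix proteoglycan, differed by 0.62, 0.68 and 0.83. Among the lower values, the transcription factor FOXC1 stood at -0.73, the phosphatase DUSP1 at -0.60, the estrogen sulfotransferase SULT1E1 at -0.65 and the tight junction gene CLDN11 at -0.50. SHISA3, PHACTR2, GLIPR1 and B2M, the light chain of class I histocompatibility molecules, stood at -0.89, -0.64, -0.54 and -0.51. None of these genes passed the threshold.

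By gene list, markers of skeletal and heart muscle, a cell type outside the kidney, were higher in PKHD1-/- as a group by camera. Of 28 members measured, 25 had a positive value, and the median was 0.23 (adjusted p = 1.47e-08, and adjusted p = 0.834 with an estimated correlation). MYL1, a myosin light chain, and TNNC2, a troponin, stood at 1.22 and 0.94. Markers of neurons were also higher as a group, with a median of 0.04 (adjusted p = 0.0359, and adjusted p = 0.834 with an estimated correlation). DCX, a neuronal microtubule protein, stood at 0.39, and 22 of 32 members were positive. In the value table, which adds no offset, the muscle median was 0.79 and the neuron median 0.11, and with 75th percentile scaling the neuron median was 0.15. Leaving out either forskolin array gave a muscle median of 0.35, and the neuron median was 0.071 without either flow array and 0.037 without either static array, where its call ended.

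Immediate early genes were lower as a group, with 25 of 32 members negative and a median of -0.08 (adjusted p = 0.00615, and adjusted p = 0.834 with an estimated correlation). EGR1, a zinc finger transcription factor, stood at -0.56 ± 0.16. Genes of fibrosis and TGF-beta signalling were lower, with 24 of 32 negative and a median of -0.12 (adjusted p = 0.0333, and adjusted p = 0.834 with an estimated correlation). The smooth muscle actin ACTA2 stood at -0.64 ± 0.36. Cell cycle genes were lower, with 22 of 36 negative and a median of -0.06 (adjusted p = 0.0399, and adjusted p = 0.834 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, stood at -0.33 ± 0.05. In the value table the medians of the immediate early, fibrosis and cell cycle lists were -0.21, -0.21 and -0.11, and with 75th percentile scaling the cell cycle median was -0.0057. In the 5 lists called, 0 members passed over all genes and 0 when adjusted over the list alone. The immediate early median shrank to -0.0098 without either flow array, where its call ended, and was -0.17 without either static array and -0.048 without either forskolin array. The fibrosis median was -0.017, -0.25 and -0.086 and the cell cycle median -0.052, -0.084 and -0.048 in the same 3 settings, and both calls ended in the first and the last.

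Limma called 0 of 16365 genes for genotype, and also 0 with its trend and robust settings. At an unadjusted p under 0.05 there were 528 (316 higher, 212 lower) where 818 would be expected by chance. Genotype differences that varied between cultures counted as spread in this test. Without either flow array, the immediate early and cell cycle calls ended (adjusted p = 0.772), the neuron call ended (0.106) and the fibrosis test pointed up at a median of -0.02 (0.772). The neuron call also ended without either static array (0.419), the cell cycle and fibrosis calls without either forskolin array (0.0668), and the cell cycle call in the value table (0.188) and over members above background on all arrays (0.0553). Genes that differed by at least 0.5 the same way in all 3 pairs numbered 11, and 37 with the genotype labels of the flow pair exchanged or 20 with those of the static pair exchanged, a rise that the negative correlation between these pairs given below entails.

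The second comparison asks what flow changes in organoids on the matrix. Values were higher under flow in both pairs for muscle genes, among others. MYH3 stood at 3.29 ± 0.44 (moderated SE from all 6 arrays, n = 2 pairs), from 2.55 in PKHD1-/- and 4.03 in PKHD1+/-. TNNC2 stood at 2.69 ± 0.36, and MYOD1, the transcription factor that sets muscle fate, at 2.19 ± 0.33. Values were lower in both pairs for DHRS3, an enzyme that reduces retinal, at -2.39 ± 0.32, PNOC, a neuropeptide precursor, at -1.92 ± 0.21, and GUCY1A1 at -1.66 ± 0.08. The rule that named these genes requires 1 sign in 2 of 2 pairs, which 45.3% of all genes tested had. None of them passed the threshold, with adjusted p from 0.281 (GUCY1A1) to 0.536 (MYOD1). FOS stood at -0.06 ± 0.49, from -0.85 in PKHD1-/- and 0.73 in PKHD1+/-, and RAC1 at -0.36 ± 0.16 (adjusted p = 0.946), negative in 2 of 2 pairs.

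Other high values were those of the muscle genes MYL1, ACTC1, SMPX, TNNC1, ACTA1 and TNNT1, from 2.13 to 3.14, and of MT1P3, a metallothionein pseudogene, at 3.04 ± 0.67. Other low values were those of TCF21, a transcription factor of podocytes and stroma, at -1.44, CXCL14, a chemokine, at -1.52, LCP1, an actin-bundling protein, at -1.58, and TDO2, which degrades tryptophan, at -1.35. G0S2, an inhibitor of fat breakdown, SHISA3 and CLDN11 stood at -1.93, -1.44 and -1.39. None of these passed.

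Muscle markers were higher under flow as a group by camera, with 25 of 28 members positive and a median of 0.82 (adjusted p = 7.46e-20, and adjusted p = 0.349 with an estimated correlation). The median was 2.32 in the value table and 1.72 over members above background on all arrays. None passed over all genes, and 14 were higher when adjusted over the list alone. Cartilage and bone markers were higher, with 20 of 24 positive and a median of 0.43 (adjusted p = 3.96e-12, and adjusted p = 0.329 with an estimated correlation). Adjusted over the list alone, 8 were higher, among them EPYC, a cartilage proteoglycan, at 1.44 ± 0.11, and the collagens COL9A1 and COL2A1 at 1.26 ± 0.09 and 1.77 ± 0.40. Neuron markers were higher, with 27 of 32 positive and a median of 0.16 (adjusted p = 3.84e-08, and adjusted p = 0.329 with an estimated correlation), and 0 passed when adjusted over the list alone. DCX stood at 1.56 and SYT4, a synaptotagmin, at 1.17. Markers of melanocytes and glia were higher, with 8 of 9 positive and a median of 0.16 (adjusted p = 0.0255, and adjusted p = 0.559 with an estimated correlation). S100B, a calcium-binding protein of glia, was the 1 member past when adjusted over the list alone, at 0.64 ± 0.06. The medians of neuron, melanocyte and cartilage markers were 0.48, 0.47 and 1.002 in the value table, while with 75th percentile scaling the neuron and melanocyte medians were 0.094 and 0.055, and over members above background on all arrays the melanocyte median was 0.095. The melanocyte median was 0.018 and 0.056 without the PKHD1-/- flow or static array, where its call ended, and 0.30 without either PKHD1+/- array. The neuron median was 0.10 without the PKHD1+/- static array.

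Among kidney cell types, endothelial markers were lower as a group, with 20 of 24 negative and a median of -0.15 (adjusted p = 1.36e-06, and adjusted p = 0.349 with an estimated correlation). Adjusted over the list alone, 3 members were lower, among them EMCN, a sialomucin of capillaries, at -0.86 ± 0.09 and EGFL7, an endothelial secreted protein, at -0.49 ± 0.08. Podocyte markers were lower, with 16 of 21 negative and a median of -0.10 (adjusted p = 0.0135, and adjusted p = 0.640 with an estimated correlation). TCF21 was the 1 member past when adjusted over the list alone, and WT1, a podocyte transcription factor, stood at -0.80 ± 0.30. Proximal tubule markers were higher, with 20 of 28 positive and a median of 0.07 (adjusted p = 0.0101, and adjusted p = 0.640 with an estimated correlation). GATM, which makes a creatine precursor, and the amino acid transporter gene SLC3A1 stood at 1.33 ± 0.51 and 1.06 ± 0.56. The endothelial, podocyte and proximal tubule medians were -0.44, -0.20 and 0.25 in the value table, and with 75th percentile scaling the first 2 were -0.25 and -0.19. The proximal tubule median turned to -0.03 when arrays were scaled to their 75th percentile, a scaling that moved the median of all genes by -0.11. Without the PKHD1-/- flow array the endothelial median was -0.050 and its call ended, and it was -0.30 without the PKHD1+/- flow array and -0.086 without the PKHD1-/- static array. The podocyte median nearly vanished without the PKHD1+/- flow or static array, at -0.027 and -0.0042, where its call ended, and was -0.23 and -0.21 without the PKHD1-/- flow or static array. The proximal tubule call ended at medians of 0.063, 0.058 and 0.017 without the PKHD1-/- flow, PKHD1+/- flow and PKHD1-/- static arrays.

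Cell cycle genes were higher under flow, with 28 of 36 positive and a median of 0.10 (adjusted p = 0.000181, and adjusted p = 0.538 with an estimated correlation), and TOP2A, at 0.74 ± 0.07, passed when adjusted over the list alone. Genes of the unfolded protein and amino acid stress responses were higher, with 23 of 31 positive and a median of 0.17 (adjusted p = 0.00207, and adjusted p = 0.349 with an estimated correlation). HSP90B1, a chaperone of the endoplasmic reticulum, stood at 0.57 ± 0.09. Cholesterol synthesis genes were higher, with 15 of 22 positive and a median of 0.22 (adjusted p = 0.00793, and adjusted p = 0.416 with an estimated correlation). CYP51A1 and FDFT1, enzymes of sterol synthesis, stood at 0.34 and 0.31. Heat shock genes were higher, with 13 of 18 positive and a median of 0.11 (adjusted p = 0.0252, and adjusted p = 0.458 with an estimated correlation). CRYAB, a small heat shock protein also made in muscle, stood at 0.63 ± 0.06 and was the 1 member past when adjusted over the list alone. Calls ended without the PKHD1+/- flow or static array at medians of 0.024 and 0.0081 for cholesterol synthesis, 0.017 and 0.22 for heat shock, and 0.076 and 0.031 for the cell cycle. Without the PKHD1-/- flow or static array the cell cycle median was 0.17 and 0.17, and heat shock was 0.18 without the latter. The stress response call ended at a median of 0.056 without the PKHD1-/- flow array.

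The shear stress list did not pass as a group (median -0.05, adjusted p = 0.185). Adjusted over the list alone, 2 of its 27 members were higher: HMOX1, which degrades heme, at 1.00 ± 0.11, and CYP1B1, a cytochrome P450 enzyme, at 1.03 ± 0.22. The 6 lower members were CCL2, a chemokine, at -1.45 ± 0.17, SMAD6 and SMAD7, inhibitors of TGF-beta family signalling, at -0.83 and -0.59, PTGIS, the prostacyclin synthase, at -0.75, PIEZO1, a mechanosensitive channel, at -0.49, and NOS3, the endothelial nitric oxide synthase, at -0.32. The immediate early list did not pass either, with a median of -0.03 (adjusted p = 0.948).

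Metallothionein genes, which encode zinc-binding and copper-binding proteins, were examined after their values were seen. All 11 genes of the MT1 and MT2 group that lay above background on all arrays had higher values with flow in both genotypes. Their median difference was 3.08 in PKHD1-/- and 1.94 in PKHD1+/-, and it kept its sign under 75th percentile scaling, with no background correction and in the value table. The genotypes already differed without flow: PKHD1-/- minus PKHD1+/- had a median of -1.53 in static culture and -0.22 under flow. Shared sequence between probes of this family could not be tested, so the 11 genes may not be independent readings. MT1M stood at 1.51 ± 0.08 and was the 1 gene past the threshold with limma's trend and robust settings. MT3, the brain form, stood at -0.23 ± 0.17.

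Limma called 0 of 16365 genes for flow, with 975 at an unadjusted p under 0.05 (538 higher, 437 lower). From the authors' value table limma called 29, of which 26 were higher and 3 lower, among them MYH3, MYOD1, COL9A1, MT1M, DHRS3 and PNOC, of which COL9A1 and MT1M were chosen after their values were seen. The stress response (adjusted p = 0.323) and endothelial (0.0790) calls ended without the PKHD1-/- flow array, the cell cycle, cholesterol, heat shock and podocyte calls without the PKHD1+/- flow (0.287 to 0.611) or static (0.421 to 0.424) array, and the proximal tubule and melanocyte calls without the PKHD1-/- flow (0.196 and 0.595) or static (0.696) array, the former also without the PKHD1+/- flow array (0.0587). In the value table the cell cycle, stress response, cholesterol and heat shock calls ended (0.152 to 0.483), the podocyte call ended with 75th percentile scaling (0.164), and the melanocyte call ended over members above background on all arrays (0.0594).

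The third comparison asks what forskolin, which raises cyclic AMP and is used to drive cyst growth, changes against static culture. Genes of the muscle contractile apparatus rose most. ACTA1, the skeletal actin, rose by 6.02 ± 0.37 on the log2 scale (moderated SE from all 6 arrays, n = 2 pairs), with adjusted p = 0.0434 by limma. Its rise was 5.39 in PKHD1-/- and 6.65 in PKHD1+/-. TNNC2 rose by 5.57 ± 0.36 and MYH3 by 5.46 ± 0.44. VGF, a secreted neuropeptide precursor and a known target of CREB, rose by 4.24 ± 0.32. MMP7, a matrix protease, fell by 2.45 ± 0.08, and GUCY1A1 and GUCY1B1, the subunits of soluble guanylate cyclase, changed by -2.08 ± 0.08 and -2.04 ± 0.12. By the rule that named these genes, each moved the same way in 2 of 2 pairs, as did 72.0% of all genes tested.

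MYH8, a perinatal myosin, TNNC1, TNNT1, MYL4, an atrial myosin light chain, ENO3, the muscle enolase, and MYBPH, a myosin-binding protein, also rose, by 4.12 to 4.82. TSPAN12, a coreceptor of Norrin signalling, fell by 2.24, SULT1E1 fell by 2.22 and CLTC, the clathrin heavy chain, fell by 1.93. PCDH18, a protocadherin, fell by 1.91, GASK1B fell by 1.88, DKK1, a WNT inhibitor, fell by 1.85 and TDO2 fell by 1.82. FOS stood at -3.49 ± 0.49, negative in 2 of 2 pairs, and did not pass (adjusted p = 0.0747). RAC1 stood at -0.05 ± 0.16.

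Muscle markers rose as a group by camera, with a median of 2.65 and 28 of 28 members positive (adjusted p = 7.82e-17, and adjusted p = 0.543 with an estimated correlation). Of these, 11 rose over all genes, and 23 when adjusted over the list alone. The muscle regulators MYOG and MYOD1 stood at 2.66 (adjusted p = 0.0426) and 3.70 (adjusted p = 0.0518). The muscle median was 4.60 in the value table. Cholesterol synthesis genes were higher, with 18 of 22 positive and a median of 0.27 (adjusted p = 0.00349, and adjusted p = 0.543 with an estimated correlation). MVK, the mevalonate kinase, rose over all genes by 1.01 ± 0.06, and 8 members were higher and 2 lower when adjusted over the list alone. The median was 0.48 without the PKHD1-/- static array and 0.53 in the value table, and this group call ended when arrays were scaled to their 75th percentile (adjusted p = 0.770).

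General epithelial markers were lower as a group, with 20 of 24 negative and a median of -0.32 (adjusted p = 0.000134, and adjusted p = 0.543 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. SPINT1, a protease inhibitor, the keratin KRT18, and CLDN4, a tight junction protein, stood at -1.34, -1.28 and -1.08. The shear stress list was lower, with 21 of 27 negative and a median of -0.23 (adjusted p = 0.00241, and adjusted p = 0.543 with an estimated correlation), and its median was 0.0011 under 75th percentile scaling and -0.59 in the value table, where the epithelial median was -0.58. SMAD7 fell over all genes by 0.88 ± 0.07, and 4 members were lower when adjusted over the list alone. Among them PKD2, a cation channel mutated in dominant polycystic kidney disease, stood at -1.88 ± 0.21 (adjusted p = 0.0604).

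The list of cyclic AMP and CREB targets did not pass as a group (median 0.08, adjusted p = 0.536), with VGF past over all genes. Adjusted over the list alone, 4 of its 35 members were higher, among them SST, the somatostatin gene, at 3.78 ± 0.34 and CREM, a cyclic AMP responsive transcription factor, at 0.87 ± 0.17. The 3 lower members were FOS, PRKAR2B, a regulatory subunit of protein kinase A, at -1.06 ± 0.18, and PRKACB, a catalytic subunit, at -0.52. The immediate early list did not pass (adjusted p = 0.573), and FOS, EGR1 and KLF10 were lower when adjusted over the list alone, EGR1 at -2.08 ± 0.19. The fluid and chloride transport list did not pass (median -0.01, adjusted p = 0.806), and ANO6, a membrane scramblase and channel, was the 1 member past when adjusted over the list alone, at -0.67.

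**Figure D2:**
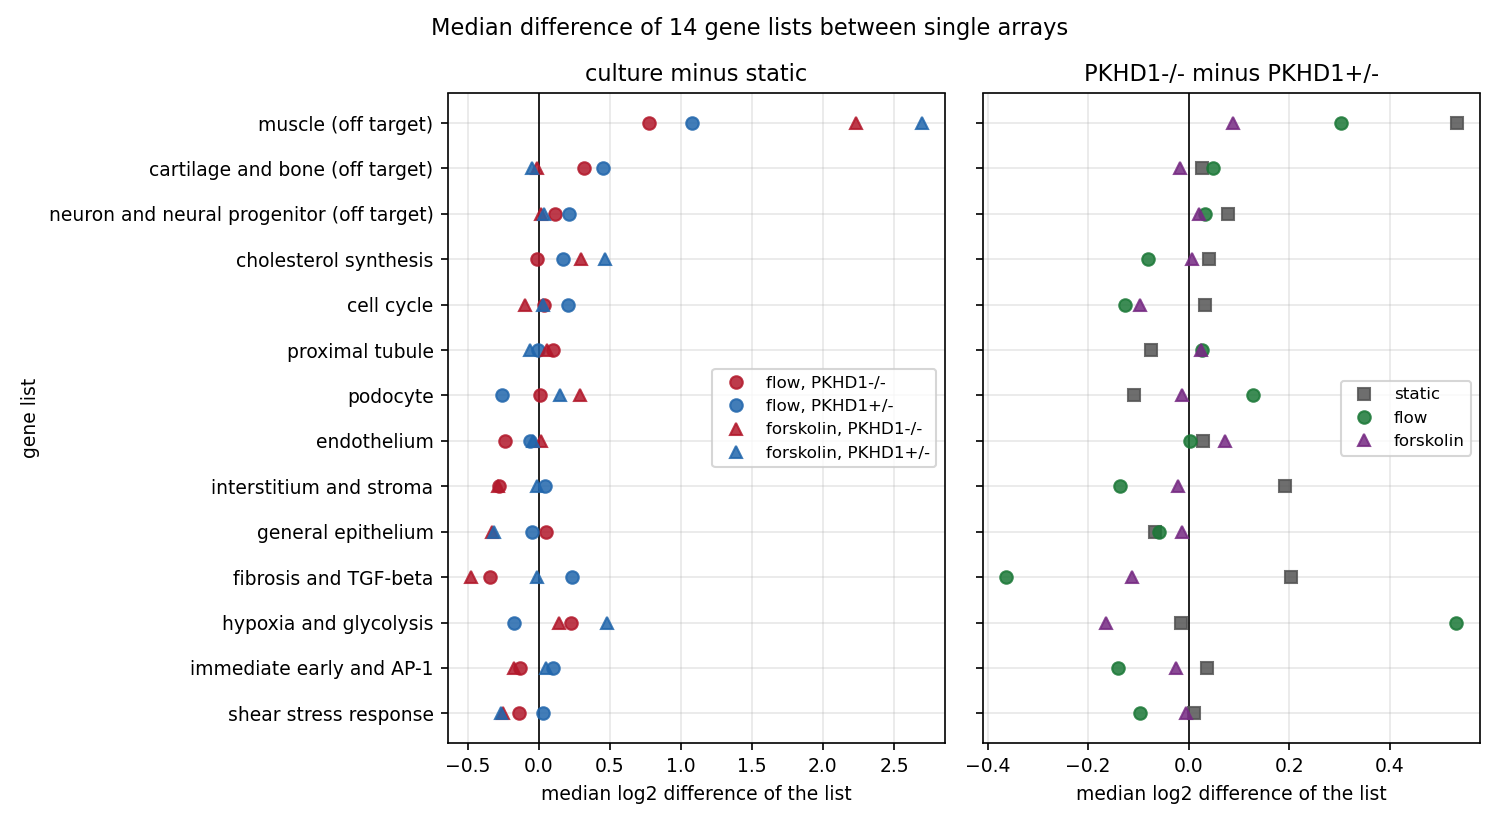
Median log2 difference (horizontal axes) of 14 gene lists between single arrays, with culture minus static in each genotype in the left panel and PKHD1-/- minus PKHD1+/- in each culture in the right panel, and 1 point per pair of arrays. Muscle markers lie highest in the left panel, at 2.23 and 2.70 with forskolin, and the fibrosis list lies at -0.36 under flow and 0.20 in static culture in the right panel.

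Limma called 184 genes for forskolin, 125 higher and 59 lower, or 1.12% of those tested. Both forskolin arrays came from another array run than the rest and may lack the matrix, so forskolin, run and substrate cannot be told apart. The count was 0 when any 1 of the 6 arrays was left out, 8 with cyclic loess, in which none of the 20 named genes passed, and 6757 (5895 higher, 862 lower) with 75th percentile scaling, which moved the median of all genes by 0.31.

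Whether flow acts differently on the mutant is the question the design puts, and with 1 array per group it could be described but not tested. COL1A1, a chain of type I collagen, stood at -3.48 with flow in PKHD1-/- and at 2.04 in PKHD1+/-, a difference of -5.52. The contractile genes MYL9 and TAGLN, known from smooth muscle, differed by -4.61 and -3.70, and PFN1, an actin-binding protein, by -3.93. SLC2A1, the glucose transporter GLUT1, stood at 0.77 in PKHD1-/- and -1.39 in PKHD1+/-, a difference of 2.15. The proximal tubule genes PDZK1 and SLC3A1 stood at 1.87 and 2.01 in PKHD1-/- and at -0.09 and 0.10 in PKHD1+/-.

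The other lowest differences were those of YWHAE, an adaptor protein of the 14-3-3 family, at -4.37, BSG, a membrane glycoprotein, at -4.06, CRABP1, which binds retinoic acid, at -4.01, PKM, a pyruvate kinase, at -3.98, BANF1 at -3.64 and IGFBP4 at -3.56. The other highest were those of TCEAL8 at 3.11, CLDN12 at 2.78, AK3L1, an adenylate kinase now named AK4, at 2.20, AFP, alpha-fetoprotein, at 2.05, MT1P3 at 1.89, MRPL11, a mitochondrial ribosomal protein, at 1.89 and HOXA9 at 1.82. For TCEAL8, CLDN12 and MRPL11 the PKHD1+/- flow array lay apart from the other 5, at 8.60, 6.49 and 7.02.

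By list, the fibrosis and TGF-beta genes had a median of -0.34 with flow in PKHD1-/- and 0.24 in PKHD1+/-. Their median difference of -0.69 lay below all 10000 random lists. Members of a list can vary together, which such percentiles do not allow for. Hypoxia and glycolysis genes had medians of 0.23 and -0.17, with a difference of 0.55 above all random lists. PKM, a member of that list, went the other way. Immediate early genes had medians of -0.13 and 0.10 (difference -0.18, percentile 0.08), and primary cilium genes had medians of 0.09 and -0.08 (difference 0.16, percentile 99.8). Stromal markers had medians of -0.28 and 0.04 (difference -0.38, below all random lists).

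Within cultures, genotype differences of at least 2-fold were seen for 171 genes under flow (45 higher and 126 lower in PKHD1-/-), 110 in static culture (71 and 39) and 143 with forskolin (76 and 67), of 14741 genes. From the value table they numbered 1738 (116 and 1622), 726 (431 and 295) and 1356 (1098 and 258), and with 75th percentile scaling the forskolin pair turned to 49 higher and 122 lower. Fibrosis genes had a genotype median of -0.36 under flow, below all random lists, 0.20 in static culture, above all random lists, and -0.11 with forskolin. Hypoxia genes had medians of 0.53, -0.02 and -0.17. Muscle markers had medians of 0.30, 0.53 and 0.09.

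Across these genes, the genotype difference under flow correlated with that in static culture at Pearson r = -0.357 (95% bootstrap interval -0.392 to -0.324, Spearman -0.356). It correlated with that with forskolin at -0.062, and the static and forskolin differences correlated at 0.081. The flow responses of the genotypes correlated at 0.045 and the forskolin responses at 0.712. These 5 correlations run across genes, which are not independent replicates. Of the 40 genes that differed at least 2-fold between genotypes under flow and in static culture, 8 did so the same way.

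**Figure D3:**
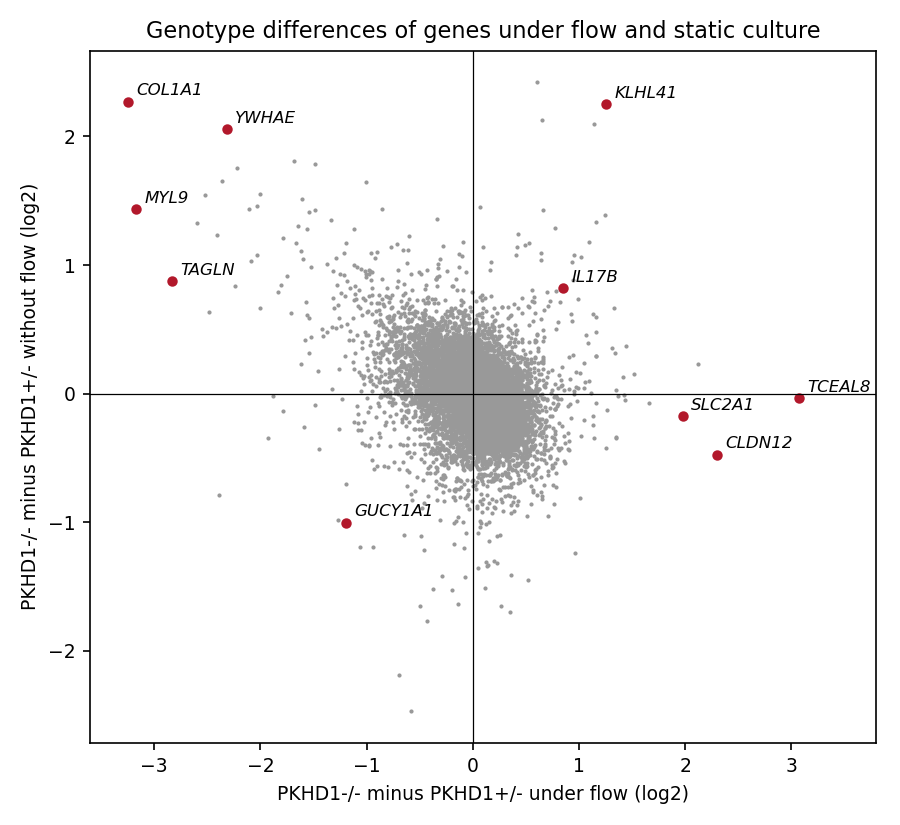
Difference of PKHD1-/- minus PKHD1+/- in log2 intensity under flow (horizontal axis) and in static culture (vertical axis), with 1 point per gene above background on all 6 arrays and 10 genes named. The cloud slopes downward (r = -0.357), with COL1A1 at -3.25 under flow and 2.27 in static culture, while GUCY1A1 and IL17B have 1 sign in both.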

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

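The tests for exchanged labels and for more proximal tubule cells, the count of muscle genes outside the contractile families and the readings of brightly measured members and of members above background were chosen only after the results were seen. Among the genes named for the largest or smallest difference of flow responses, 17 had flow responses of opposite sign in the 2 genotypes. So did the medians of the 4 lists given below. Other named genes, FOS among them, and other lists, stromal markers among them, also had opposite signs and are not in these counts. Of all genes tested, 45.3% had the same sign of flow response in both genotypes. The differences of flow responses were not tested, since each rests on single arrays.

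The difference of the flow responses, PKHD1-/- minus PKHD1+/-, was -5.52 for COL1A1, -4.61 for MYL9, -4.37 for YWHAE, -4.06 for BSG, -4.01 for CRABP1 and -3.98 for PKM. It was -3.93 for PFN1, -3.70 for TAGLN, -3.64 for BANF1 and -3.56 for IGFBP4. It was 3.11 for TCEAL8, 2.78 for CLDN12, 2.20 for AK3L1, 2.15 for SLC2A1, 2.05 for AFP, 1.97 for PDZK1 and 1.82 for HOXA9. As list medians it was -0.69 for fibrosis and TGF-beta genes, 0.55 for hypoxia and glycolysis genes, -0.18 for immediate early genes and 0.16 for primary cilium genes.

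Genotype differences ran opposite ways on the flow and static arrays (r = -0.357 across genes). The tables argue against noise of single probes, since the difference of flow responses correlated at 0.470 between the 2 probes of a gene (interval 0.397 to 0.541, 1683 genes), and against normalization, since r was -0.329 or lower under 4 other scalings. Position on the array could account for 2.01% of the variance (interval 1.72 to 2.48), which leaves a small part open. The count as labelled was 0 genes (highest other 0), so all 10 splits of the arrays into 3 and 3 give as many by construction, and 10 splits are too few for a share under 0.05. An exchange of labels within the flow or static pair cannot be told apart from a flow response that differs between genotypes. Nor can either be told apart from variation between single samples, since each group holds 1 array. The differing flow response, which the design names, stays untested. Of the 200 genes with the largest forskolin difference, 38.0% (interval 31.3 to 45.1) had the same sign under flow and 63.0% in static culture.

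Muscle genes were higher on the forskolin arrays than on the static arrays, with a list median of 2.65 (interval 0.88 to 3.88). The tables argue against a lower share of kidney cells only in a form that raises markers of all other cell types alike. The highest median of 4 such lists was 0.019 (interval -0.042 to 0.075). These were stroma and endothelium, which kidney also holds, and neuron and cartilage. Members near the floor cannot show a rise. The 5 neuron and cartilage members above the 75th percentile of intensity had a median of 0.62 (interval -0.01 to 1.32). Their intensity was the mean of the static and forskolin arrays, which favours members that rose. The 53 above background on all arrays had a median of -0.015 (interval -0.10 to 0.069). None of the 5 reached the interval of the muscle members above background on all arrays, 1.91 to 4.12. General epithelial markers were lower, at a median of -0.32, and a lower kidney share through more muscle cells stays open. Shared sequence among contractile families was judged by the 12 members outside the myosin, troponin and actin families. Their median was 1.47, over the 1 set beforehand, though the interval, 0.29 to 2.65, reaches below 1. That interval lies above 0.2, the most this explanation was said to allow, and 2 of these members, MYOG and CKM, rose over all genes, 10 when adjusted over the list alone. The 12 members lie outside the families by choice, so they bear only on whether shared sequence is the whole cause of the list's rise. Their values argue against that, though the interval reaches below 1 and takes the genes as independent readings. Whether shared sequence adds to the rise of members within the families was not tested. Forskolin, the substrate, more muscle cells and the array run stay open, and the run cannot be told apart from the culture because 0 forskolin arrays share a run with another culture.

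Metallothionein genes were higher on the flow arrays, with median differences of 3.08 in PKHD1-/- and 1.94 in PKHD1+/-. Metal exposure could raise them, and SLC30A1, a zinc exporter gene that metal also induces, stood at 0.097 and 0.12, between the bounds set beforehand. The tables argue against more proximal tubule cells as the whole cause in PKHD1+/-, where the 8 members of that list above the 75th percentile of intensity had a median of 0.0028 (interval -0.34 to 0.58) and the metallothionein interval ended at 2.07 and began above 1 (full list -0.0041). In PKHD1-/- more proximal tubule cells could raise them, since these 8 members had a median of 0.50 with an interval of -0.13 to 2.01, against 1.55 to 3.41. These intervals take the genes of a list or family as independent readings. Flow itself, which the design names, stays open and untested.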

How the results depend on the processing

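Leaving out each array for the list tests was chosen only after the data were seen. The genotype count was 0 under every alternative run but 1: at an unadjusted p under 0.01 and 2-fold it was 2 (IL17B, GUCY1A1). The flow count was 0 except for 29 (26 higher, 3 lower) in the value table, 1 (MT1M) with trend and robust settings, and 69 at an unadjusted p under 0.01 and 2-fold. Against 184 (125 higher, 59 lower), the forskolin count was 6757 (5895 higher, 862 lower) with 75th percentile scaling, 8 with cyclic loess, 835 (433 and 402) with an offset of 10, 758 (332 and 426) in the value table and 76 with no filter. It was 1193 (601 and 592) with trend and robust settings, 1303 (717 and 586) at an adjusted p under 0.1, 400 (216 and 184) at an unadjusted p under 0.01 and 2-fold, 7 against flow, and 667 (384 and 283) against the mean of flow and static, 182 of them among the 184. It was 0 with the 4 forskolin and static arrays alone and ran from 0 to 0 without each array, fits with fewer arrays; the cause of the other shifts was not tested. With 1 array of a culture left out, the remaining array of that culture is assumed to vary like the other cultures. For genotype, leaving out either array of a culture gave the same list medians.

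Of the list calls, 5 for genotype, 11 for flow and 4 for forskolin, 0, 0 and 0 remained with an estimated correlation and 0, 0 and 2 with fry. With 75th percentile scaling 15 lists passed for genotype and 7 for forskolin, and 7 passed for forskolin from the value table. Without each array the counts ran from 2 to 5, 9 to 13 and 4 to 7.

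Values near 0 changed sign, and the cause was not tested. For PKHD1, the genotype difference was 0.098 by the brightest probe, 0.027 without the 2 static arrays and -0.091 to 0.027 without each array, and the flow difference -0.115 to 0.052. Its forskolin difference was 0.027 with 75th percentile scaling and 0.48 by the brightest probe. FOS ran from -0.85 to 0.73 for flow without each array. RAC1 for forskolin was 0.0019 with 75th percentile scaling, 0.28 in the value table, 0.31 against flow, 0.13 against the mean of flow and static, and -0.27 to 0.17 without each array. The genotype median of the fibrosis list ran from -0.25 to -0.017 without each array.

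In the value table, which adds no offset, genes differing at least 2-fold numbered 1738, 726 and 1356 between genotypes (flow, static, forskolin), 1326 and 1495 between flow and static (PKHD1-/-, PKHD1+/-) and 3421 in the difference of flow responses. The flow and static genotype differences correlated from -0.357 to -0.329 under these alternatives. The dim forskolin arrays, with median spots 16.5 and 21.1 units above the blanks, limit what can be read for weak genes.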

Other observations

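Other genes of the fixed lists passed the forskolin threshold. DLK1, a stromal and progenitor cell gene, rose by 3.91 ± 0.30 on the log2 scale (n = 2 pairs), and CRYAB, a small heat shock protein, rose by 2.56 ± 0.06. IFI6, an interferon-induced gene, rose by 1.36 ± 0.10 while IFI44L, another, fell by 0.82 ± 0.07, and the interferon list as a group did not pass (adjusted p = 0.944). EMCN fell by 1.47 ± 0.09, and the endothelial list did not pass (median 0.02, mean -0.10, adjusted p = 0.894). SDF2L1, a chaperone cofactor, rose by 0.78 ± 0.06. MT1E, a metallothionein, rose by 2.11 ± 0.13, chosen after its values were seen.

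When adjusted over the list alone, the hypoxia genes EGLN3, PFKFB4 and CA9 were higher with forskolin, at 1.70 ± 0.20, 1.56 ± 0.23 and 1.20 ± 0.11, and that list did not pass (median 0.16, adjusted p = 0.106). The matrix and stromal genes LUM, POSTN and COL3A1 were lower, at -1.80, -1.21 and -1.06. TMEM67, a cilium gene, was lower at -0.61 ± 0.06, and the primary cilium list did not pass (median -0.13, adjusted p = 0.0519). CDH6, a cadherin of the developing nephron, was lower at -2.27 ± 0.26, and the proximal tubule list did not pass (adjusted p = 0.573). White blood cell and macrophage markers did not pass in any comparison (adjusted p = 0.773 for genotype, 0.767 for flow and 0.944 for forskolin).

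Single arrays stood apart at some genes, chosen after their values were seen. RPL38, CBX1, EIF4A2 and A2M read 9.25, 5.95, 6.34 and 6.10 on the PKHD1-/- forskolin array, and differed from the PKHD1+/- forskolin array by -3.73, -4.03, -3.98 and -4.88. Median, mean and camera direction differed in sign for lists that did not pass. For genotype these were stress response, cholesterol, heat shock, podocyte, nephron progenitor, endothelial and white blood cell lists. For flow they were hypoxia, fluid transport, distal tubule, collecting duct and nephron progenitor lists, and for forskolin heat shock, collecting duct, endothelial and neuron lists. Of the 4224 probes with no gene name, 2984 lay above background on all arrays and were not analysed here.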
